A study of Citrus sinensis and Citrus junos and Citrus trifoliata with 12 samples.

How the data were processed

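RNA was measured in 12 libraries: roots, stems and leaves of grafted trees on 2 rootstocks, with 2 libraries for each of the 6 groups. Per the labels' protocols, poly(A) RNA was selected on oligo(dT) beads, broken to fragments of roughly 200 bases, copied to cDNA from random primers and amplified by PCR, and per the series' design text it was sequenced on a BGISEQ-500. The labels give one developmental stage, 140 DAF, for every library. The aligner, the counting tool, the annotation and the genome build are not given in the sources used here, nor is the strandedness of the kit, so overlapping genes and near-identical copies are uncertain at the level of single genes.

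The authors deposited one table per library, and per the file headers each gives a gene ID, its transcripts, a length, an expected (estimated) count and an FPKM. The deposited expected counts are not scaled to depth, and between 73.1% and 76.5% of the listed values were whole within 0.005, and the rest were not, as happens when reads are divided between genes or transcripts. The deposited FPKM values are scaled by the authors by gene length and library size; they were reproduced from the counts with a length shortened by 36.4 to 36.6 bases and totals slightly above the listed ones. A gene missing from a table was taken as a count of 0, because each table lists only values above 0. Replicates were not pooled. In all 26559 IDs occurred in at least 1 library. The lowest total was 9356633 and the highest 11383332. PCR copies were not marked, so the precision given by depth covers counting error only.

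The IDs have the forms CsNgN (21578 IDs) and orange1.1tN (4981 IDs), where N stands for digits. They were compared with a table of 29331 RefSeq genes of the assembly DVS_A1.0, and 0 of 26559 matched by any identifier. The files do not pair IDs with names. The 35 gene lists fixed before the data were examined are patterns on gene descriptions, so they could not be applied and the gene list tests were not run. The rule for named genes, fixed at the same time, falls back in this case to 2 IDs per direction and comparison. They are those with the largest log2 fold change among genes with adjusted p under 0.05, a mean log2 CPM of at least 3 over the libraries compared and both libraries of one group above both of the other. For the stem minus leaf contrast the last condition was not applied.

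Expected counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (version 4.0.16, with limma 3.58.1, in R 4.3.3). Genes were filtered with filterByExpr, which kept 21261 and left 5298 untested, and library sizes were scaled by TMM. One model with 6 group means was fitted to all 12 libraries, which leaves 6 residual degrees of freedom, and contrasts were taken from it: Cj minus Pt in roots, stem and leaf, the stem effect minus the leaf effect, and leaf minus stem averaged over rootstocks. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic. CPM values use TMM-scaled library sizes. Shares of total counts use the listed totals. The TMM factors were 0.784 to 0.845 in roots, 1.14 to 1.19 in stem and 1.05 to 1.08 in leaf.

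Replicates were compared before use. A chi-square of rounded counts per degree of freedom was 2.86 to 11.8 in the 6 groups, so no pair agreed within sampling noise and none was counted as 1 library. Overlaps of calls were set beside the product of list lengths over the genes tested and Fisher's exact test. Tissue groups were formed after the data had been seen, from contrasts averaged over rootstocks with a log2 difference of at least 2 and adjusted p under 0.05: 2307 root-enriched, 576 stem-enriched and 364 leaf-enriched genes, and 2753 scion genes above root in both scion tissues with a log2 difference between leaf and stem under 1. Members with a mean log2 CPM of at least 1 in the libraries compared entered limma's camera with a preset correlation of 0.01, with an estimated correlation and limma's fry beside it, adjusted over 12 tests. Principal components were taken from log2 CPM. Genes listed per library were also counted after thinning every library to 9356624 counts. For runs of neighbouring IDs, calls were shuffled 1000 times over the tested IDs of the CsNgN form, and pairs of consecutive tested IDs with the same start (up to the letter g) that were called in one direction were counted.

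The fits were tested on simulated counts drawn from the real means, with 200 changed genes for each comparison. A spread that differs between tissues was not tested in this way. The simulations therefore cannot tell whether an estimate of spread shared by all tissues calls too many stem genes. Each gene had the same simulated spread in all tissues, so the recovery figures cannot rank the tissues. In the data 10994 genes were called in roots and 11633 for leaf minus stem. The cut-off on p moves with the number of changed genes, so the figures hold for 200 changed genes only. In each comparison the share of false calls was above the 0.05 set as the threshold for adjusted p. For roots (20999 genes run) 50% of 2-fold and 74% of 4-fold changes were recovered, with 12 false calls among 136. For stem (20997 genes) these values were 68% and 83%, with 19 false among 170; for leaf (21004 genes) 61% and 89%, with 14 among 164; for the stem minus leaf contrast (20998 genes) 31% and 68%, with 7 among 106; and for leaf minus stem (20911 genes) 79% and 95%, with 23 among 197.

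Alternatives chosen before the data were examined were DESeq2's size factors in place of TMM, no filter on low counts, DESeq2's Wald test (version 1.42.0), fits of only the tissue or tissues compared, the replicate number as a block, a minimum absolute log2 fold change of 1, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM of at least 1 in at least 2 libraries, and leaving out each replicate in turn. In the last case the lone library of a group is assumed to vary like the other groups. Added after the data were seen were fits without the 2 most abundant root genes and fits of only the 8 scion or only the 8 root and stem libraries, the remaining settings for genes shared by stem and leaf, and all settings for the tissue groups. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.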

Results

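Gene expression was measured in the roots, stems and leaves of grafted orange trees that carried one scion on 2 rootstocks. The scion was the navel orange 'Lane Late' (Citrus sinensis). The rootstocks were Ziyang xiangcheng (Citrus junos, written Cj) and trifoliate orange (Poncirus trifoliata, written Pt). In a grafted tree the roots belong to the rootstock, so the root libraries compare 2 species, while the stem and leaf libraries compare the same scion on different roots. The trees were planted in one orchard in 2009 and the libraries were sequenced in 2015. The series title names saline-alkali stress as its subject. The labels give no stressed and unstressed groups, so every comparison is between rootstocks or between tissues. Each of the 6 groups had 2 libraries, called biological replicates by the submitters. The labels do not say whether these came from separate trees, so p-values measure the spread between these libraries.

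The 12 libraries held between 9356633 and 11383332 estimated counts. The number of genes with any estimated count ran from 20953 to 23152 per library, 17518 genes were listed in every library, and 21261 genes were tested. Stem libraries listed most genes, with 23019 ± 50.9 (SD, n = 2) on Cj and 23032 ± 170 (SD, n = 2) on Pt. Roots of Cj listed 21810 ± 24.7 genes and roots of Pt 21018 ± 91.9 (SD, n = 2 each). After thinning to equal depth the roots still differed, at 21700 ± 58.7 and 20944 ± 88.4 genes (SD, n = 2 each). The IDs could not be paired with gene names here, so genes are given by ID and no function is stated for any of them.

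The libraries separated first by root against scion, where tissue and species differ together. The first principal component held 77.8% of the variance and parted all 4 root libraries from all 8 scion libraries. The second (10.2%) parted leaf from stem. It also parted Cj roots (scores -22.6 and -22.3) from Pt roots (43.1 and 38.8). The third (7.03%) parted Cj roots from Pt roots as well. The fourth (1.41%) parted the scion libraries on Cj from those on Pt. Pearson's r of log2 counts-per-million (CPM) across genes was 0.984 to 0.987 between replicates. Between rootstocks it was 0.905 to 0.910 in roots, 0.973 to 0.983 in stem and 0.973 to 0.977 in leaf. Genes are not independent replicates, so these r values are descriptive.

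**Figure D1:**
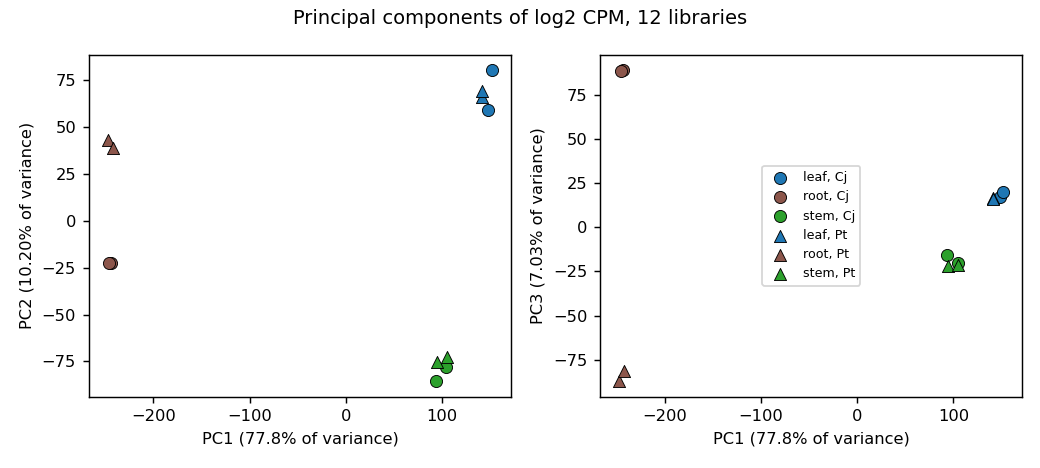
Each point is 1 library, placed by its scores on the principal components of log2 CPM (arbitrary units), with the share of variance on each axis; colour gives the tissue and shape the rootstock. Root and scion libraries part along the first component (77.8%) and leaf and stem along the second (10.2%). The roots of the 2 species part along the second and the third (7.03%).

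A single gene dominated the roots of both rootstocks. Cs7g25130 took 9.70% ± 1.09 of all counts in Cj roots and 10.3% ± 0.440 in Pt roots (SD, n = 2 each), against 0.0238% to 0.0288% in the 4 scion groups. Its level did not differ detectably between the root groups (log2 fold change -0.02 ± 0.25 SE, adjusted p = 0.991, edgeR's quasi-likelihood test). The next most abundant root gene, orange1.1t01308, took 1.33% ± 0.120 of counts in Cj roots and 2.39% ± 0.371 in Pt roots (SD, n = 2 each). It was lower in Cj roots by a log2 fold change of -0.77 ± 0.22 (SE, adjusted p = 0.0096, same test). Both IDs were singled out after their values were seen.

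The first comparison asked how the roots of the rootstocks themselves differ. Of 21261 tested genes 10994 (51.7%) passed, 5829 higher and 5165 lower in Cj roots. This balance turned on log2(FPKM + 1) (5300 higher and 5729 lower), on log2(FPKM + 0.1) (5581 and 5834) and with the root libraries alone (5900 and 5920). Large differences leaned to Cj, with 1899 genes at least 4-fold higher and 848 at least 4-fold lower in Cj roots. Orange1.1t00580 stood at 266 ± 3.15 CPM in Cj roots and 4.50 ± 0.997 CPM in Pt roots (SD, n = 2 each). Cs7g05270 stood at 101.4 ± 3.39 against 1.93 ± 0.583 CPM and had no counts in the 8 scion libraries. In the other direction, Cs2g07400 stood at 2.47 ± 0.494 CPM in Cj roots and 333 ± 46.7 CPM in Pt roots, and orange1.1t04761 at 1.04 ± 0.209 against 68.8 ± 5.01 CPM (SD, n = 2 each).

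The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. By it the log2 fold changes were 5.88 ± 0.21 (SE, adjusted p = 7.6e-09) for orange1.1t00580, 5.71 ± 0.23 (adjusted p = 2.2e-07) for Cs7g05270, -7.07 ± 0.24 (adjusted p = 7.6e-09) for Cs2g07400 and -6.03 ± 0.34 (adjusted p = 6.0e-08) for orange1.1t04761. A further 20 genes had at least 20 counts in both Cj root libraries and none in either Pt root library, and 19 showed the reverse. Without that minimum the numbers were less even. There were 752 genes listed in both Cj root libraries and neither Pt root library, and 410 showed the reverse. Libraries of all 3 species were counted on one set of IDs, so a gene whose reads align poorly in one rootstock species reads as lower there.

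Genes enriched in stem that roots also expressed were more often called higher than lower in Cj roots, and 49 of them were not called. Of 576 genes at least 4-fold higher in stem than in both root and leaf, 135 were expressed in roots; of these, 70 were higher and 16 lower in Cj roots, with a median log2 fold change of 1.02. The group passed against all other genes (adjusted p = 9.8e-04, limma's camera with a preset correlation of 0.01), and had an adjusted p = 0.889 with an estimated correlation. Root-enriched genes split 777 higher and 477 lower among 2009 expressed members (median 0.25, camera adjusted p = 0.0724, 0.0143 with the root libraries alone and 0.889 with an estimated correlation), against 4562 higher and 4618 lower among all 15845 genes expressed in roots. Leaf-enriched genes (20 higher and 16 lower of 52) and genes shared by stem and leaf (266 higher and 271 lower of 886) did not pass, with a camera adjusted p = 0.932 for each. By limma's fry the stem-enriched and the root-enriched group each had an adjusted p = 0.0404. The leaf-enriched group had 0.691 and the genes shared by stem and leaf 0.328 in that test. These tissue groups were defined on the same libraries, averaged over rootstocks, after the data had been seen.

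The second comparison asked what the rootstock changes in the leaves of the scion. Fewer genes differed in leaf than in roots: 1766 of 21261 genes (8.31%) passed, 941 higher and 825 lower on Cj, and 132 of them differed at least 4-fold, 54 higher and 78 lower. Cs1g01700, an abundant leaf transcript, stood at 1804 ± 13.1 CPM on Cj and 169 ± 17.7 CPM on Pt (SD, n = 2 each). Cs6g11700 stood at 39.9 ± 11.5 against 2.47 ± 1.11 CPM. Cs4g17240 and Cs4g17220 were nearly silent on Cj: Cs4g17240 stood at 2.22 ± 0.643 CPM on Cj and 447 ± 197 CPM on Pt, and Cs4g17220 at 0.784 ± 0.277 against 88.6 ± 46.8 CPM (SD, n = 2 each).

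By edgeR's quasi-likelihood test the leaf log2 fold changes were 3.42 ± 0.19 (SE, adjusted p = 2.5e-06) for Cs1g01700, 4.01 ± 0.33 (adjusted p = 2.0e-05) for Cs6g11700, -7.65 ± 0.47 (adjusted p = 5.2e-06) for Cs4g17240 and -6.81 ± 0.45 (adjusted p = 4.6e-06) for Cs4g17220. Leaving out Cj leaf replicate 2 or Pt leaf replicate 1 gave 938 genes each. The lean to higher genes turned without Pt leaf replicate 2 (391 higher and 472 lower, 863 in all), on log2(FPKM + 1) (767 and 798) and on log2(FPKM + 0.1) (524 and 634).

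Genes that stem and leaf express at similar levels, and at least 4-fold above root, were more often higher than lower in leaves on Cj. Of 2378 such genes expressed in leaf, 233 were higher and 73 lower (median log2 fold change 0.09), against 909 higher and 782 lower among all 17085 expressed genes. Root-enriched genes leaned the other way, with 34 higher and 87 lower of 855 (median -0.11). Limma's camera gave an adjusted p = 0.0107 for the scion group and 0.00626 for the root-enriched group with the preset correlation, and an adjusted p = 0.779 and 0.889 with an estimated correlation. Limma's fry gave an adjusted p = 0.0404 for the scion group and 0.328 for the root-enriched group. Without Cj leaf replicate 2 the root-enriched group no longer passed (camera adjusted p = 0.0849). Leaf-enriched genes (24 higher and 32 lower of 312, adjusted p = 0.560) and stem-enriched genes (12 higher and 10 lower of 217, adjusted p = 0.532) did not pass camera either. The leaf libraries on Cj stood apart from each other in the stem-enriched genes: their median log2 level relative to the 4 leaf libraries was 0.28 in replicate 1 and -0.39 in replicate 2, against 0.16 and -0.02 in the replicates on Pt. The group's median log2 fold change was -0.53 without Cj leaf replicate 1 (camera adjusted p = 3.8e-09) and 0.22 without replicate 2 (adjusted p = 7.2e-05), and leaf-enriched genes passed without replicate 1 (median 0.17, adjusted p = 0.00614).

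The third comparison asked the same of the scion stem. Here 941 of 21261 genes (4.43%) passed, 534 higher and 407 lower on Cj, and 34 differed at least 4-fold, 8 higher and 26 lower. Cs9g01630 stood at 55.0 ± 10.4 CPM on Cj and 8.04 ± 0.259 CPM on Pt, and Cs7g29040 at 41.4 ± 23.4 against 9.23 ± 0.167 CPM (SD, n = 2 each). The same run of IDs that was low in leaf on Cj was low in stem: Cs4g17240 stood at 2.25 ± 1.49 CPM on Cj and 145 ± 47.4 CPM on Pt, and Cs4g17230 at 39.9 ± 14.4 against 771 ± 215 CPM (SD, n = 2 each).

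By edgeR's quasi-likelihood test the stem log2 fold changes were 2.77 ± 0.21 (SE, adjusted p = 8.3e-05) for Cs9g01630, 2.16 ± 0.30 (adjusted p = 0.00292) for Cs7g29040, -6.03 ± 0.46 (adjusted p = 9.9e-05) for Cs4g17240 and -4.27 ± 0.29 (adjusted p = 4.5e-05) for Cs4g17230. With the 4 stem libraries alone Cs7g29040 had an adjusted p = 0.0628 (same test). Its log2 fold change was 1.43 without Cj stem replicate 1 and 2.65 without Cj stem replicate 2. None of the 4 tissue groups passed camera in stem, with an adjusted p of 0.932 for root-enriched (38 higher and 45 lower of 1011), 0.532 for stem-enriched (26 and 8 of 484), 0.0724 for leaf-enriched (15 and 22 of 193) and 0.532 for scion genes (108 and 47 of 2348). Root-enriched genes stood at a median log2 level of 0.10 and -0.11 in the replicates on Cj and 0.08 and -0.10 in those on Pt, relative to the 4 stem libraries. They passed camera as lower on Cj without Cj stem replicate 1 (median -0.12, adjusted p = 0.00405) and as higher on Cj without replicate 2 (median 0.10, adjusted p = 8.3e-04), and leaf-enriched genes passed as lower without Cj stem replicate 2 or Pt stem replicate 1 (adjusted p = 0.0247 and 0.0234).

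The stem count depended on which libraries were fitted. It was 941 with all 12 libraries, 1011 with the 8 root and stem libraries, 343 (192 higher and 151 lower) with the 8 scion libraries and 66 (30 higher and 36 lower) with the 4 stem libraries. These fits differ in residual degrees of freedom, in the genes kept by the filter and in the estimate of spread. On the same 21027 genes and with 4 residual degrees of freedom each, the root and stem libraries gave 1035 genes (582 higher and 453 lower) and the stem and leaf libraries 421 (236 higher and 185 lower). Leaving out 1 library from the fit of all 12 gave 191 (77 higher and 114 lower) without Pt stem replicate 1, 286 (136 and 150) without Pt stem replicate 2 and 1407 (901 and 506) without Cj stem replicate 2. Without Cj stem replicate 1 the counts were 48 higher and 53 lower. On log2(FPKM + 0.1) the stem count was 174, with 78 higher and 96 lower, and on log2(FPKM + 1) it was 593, with 290 and 303. The leaf count was 1766 with all libraries, 1261 with the 8 scion libraries and 1247 with the 4 leaf libraries. The biological coefficient of variation was 7.09% in roots, 14.1% in stem and 12.9% in leaf. Of the stem calls, 42 (21 higher and 21 lower) passed in every one of the fits with all libraries, with the stem libraries alone, with DESeq2 and without each stem library in turn; for leaf the number was 513 (273 higher and 240 lower) and for roots 6861 (3569 higher and 3292 lower).

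**Figure D2:**
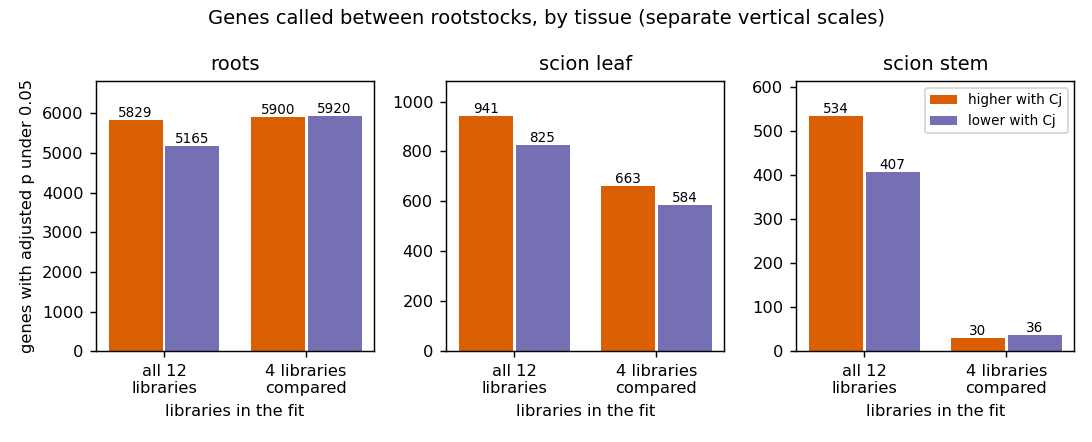
Bars give the number of genes with adjusted p under 0.05 (edgeR's quasi-likelihood test), higher or lower with Cj than with Pt, in roots, scion leaf and scion stem, from a fit of all 12 libraries or of the 4 libraries compared; each panel has its own vertical scale starting at 0. The root count is similar in both fits (10994 and 11820), while the stem count falls from 941 to 66.

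Genes that differed between rootstocks in both scion tissues mostly did so in one direction. Of the 424 genes called in stem and in leaf, 222 were higher on Cj in both and 192 lower in both, 414 in all, and 10 had opposite directions. Independent lists of the same lengths would share 23.6 higher and 15.8 lower genes. Fisher's exact test across genes (two-sided) gave p = 7.0e-162 and 8.4e-164, though genes are not independent replicates. The comparisons share no library, but they share the estimate of spread of each gene. A gene of low estimated spread is more easily called in both, which these expected numbers leave out. The labels do not say whether stem and leaf libraries came from the same trees; if they did, differences between trees would be shared by both tissues and these expected numbers would not hold. The change was larger in leaf for 295 of the 414 genes, with a median absolute log2 fold change of 0.97 in leaf and 0.81 in stem. At least 2-fold in both tissues were 48 higher and 61 lower genes, and at least 4-fold in both were 3 higher (Cs1g01700, Cs9g01630 and Cs2g21940, the last named after its values were seen) and 14 lower. The number of shared genes was 47 with each tissue fitted alone, 76 without Cj stem replicate 1, 133 without Pt stem replicate 1 and 148 without Pt stem replicate 2, and 33 genes (16 higher and 17 lower) were shared in every fit of the kind listed for stem. Across all 21261 genes, Pearson's r of the fold changes in stem and leaf was 0.20 and Spearman's rho 0.32.

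**Figure D3:**
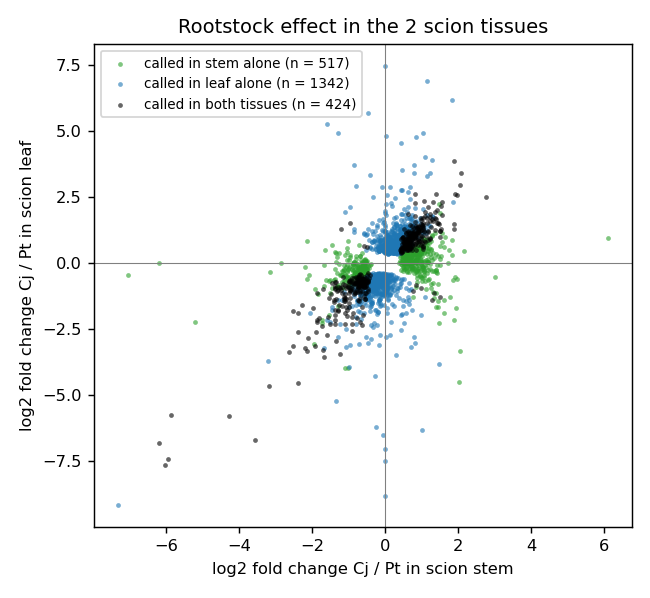
Each point is 1 gene called between rootstocks in scion stem, scion leaf or both, at its log2 fold change (Cj over Pt) in stem and in leaf; lines mark 0. Of the 424 genes called in both tissues (black), 414 lie in the lower left or upper right part of the plot.

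Among the large differences shared by stem and leaf were those of 3 consecutive IDs. Cs4g17220, Cs4g17230 and Cs4g17240 were low in all 4 scion libraries on Cj and high in all 4 on Pt. In stem Cs4g17220 stood at 0.402 ± 0.250 CPM on Cj and 30.0 ± 5.06 CPM on Pt, and in leaf Cs4g17230 stood at 12.1 ± 1.85 against 673 ± 177 CPM (SD, n = 2 each). Their log2 fold changes there were -6.21 ± 0.51 (SE, adjusted p = 9.9e-05) and -5.79 ± 0.32 (adjusted p = 2.5e-06), by edgeR's quasi-likelihood test. In roots of both rootstocks the 3 IDs stayed at or below 2.08 CPM. The IDs on either side did not share the pattern: Cs4g17210 had log2 fold changes of 0.22 ± 0.39 in stem and -0.81 ± 0.39 in leaf, and Cs4g17250 of 0.23 ± 0.13 in stem and 0.77 ± 0.13 in leaf, where it was called higher on Cj (adjusted p = 0.00328, edgeR's quasi-likelihood test). These flanking IDs were chosen after the values of the run had been seen.

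**Figure D4:**
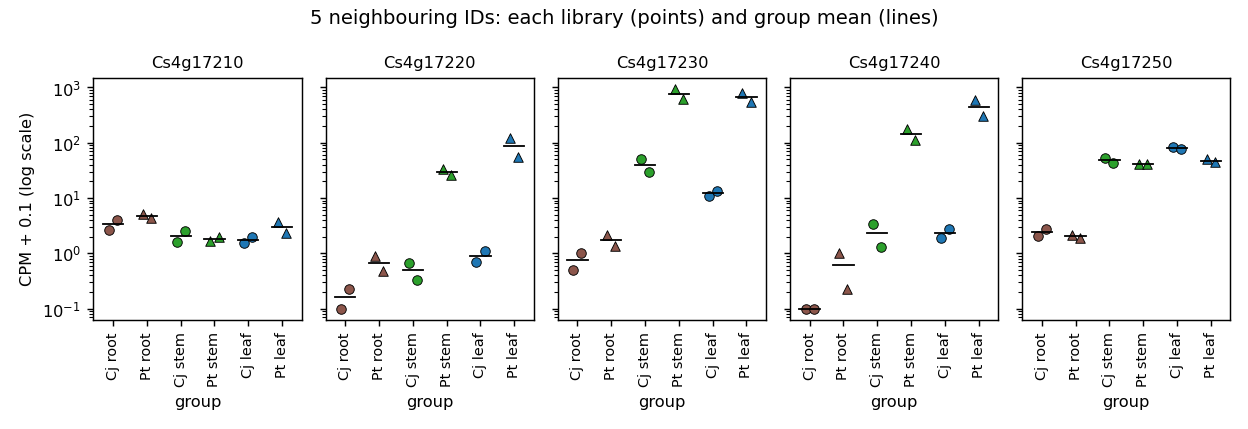
Points give CPM + 0.1 on a log axis for 5 neighbouring IDs in each of the 12 libraries, by group (brown root, green stem, blue leaf; circles Cj, triangles Pt), and lines give group means of 2 libraries. Cs4g17220, Cs4g17230 and Cs4g17240 are lower in every scion library on Cj than in any on Pt, by at least 10.9-fold, and the IDs on either side show no such gap.

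For some genes the rootstock difference was not the same in stem and leaf. The test of that contrast called 78 genes, 48 with a higher and 30 with a lower Cj effect in stem than in leaf. Of these, 50 were called between rootstocks in leaf alone, 10 in stem alone, 8 in both with one direction and 10 in both with opposite directions. Cs9g16810 stood at 1.15 ± 0.747 CPM in leaf on Cj and 16.5 ± 1.30 CPM on Pt, while in stem it stood at 72.2 ± 62.6 against 25.8 ± 4.36 CPM (SD, n = 2 each). Cs6g19380 stood at 8.87 ± 2.33 against 78.9 ± 14.0 CPM in leaf and at 40.3 ± 36.2 against 24.5 ± 0.0595 CPM in stem. Cs8g14120 went the other way, at 13.5 ± 9.83 against 1.76 ± 0.251 CPM in leaf and 11.2 ± 3.81 against 19.5 ± 2.75 CPM in stem. Cs7g18150 was called in both tissues, at 8.97 ± 1.22 against 3.11 ± 0.333 CPM in leaf and 9.76 ± 0.236 against 19.1 ± 0.252 CPM in stem (SD, n = 2 each).

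By edgeR's quasi-likelihood test the differences of the log2 fold changes, stem minus leaf, were 5.29 ± 0.83 (SE, adjusted p = 0.0208) for Cs9g16810, 3.87 ± 0.66 (adjusted p = 0.0341) for Cs6g19380, -3.75 ± 0.61 (adjusted p = 0.0252) for Cs8g14120 and -2.49 ± 0.29 (adjusted p = 0.0129) for Cs7g18150. The count of 78 was 3 with the 8 scion libraries alone (Cs3g01590, Cs5g09000 and Cs7g18150), 315 with DESeq2, 1 without Pt stem replicate 1, 26 and 29 without Pt leaf replicate 1 or 2, and 470 without Cj stem replicate 2. Its split was 26 higher and 47 lower without Cj leaf replicate 2, 12 and 14 without Pt leaf replicate 1, 22 and 7 without Pt leaf replicate 2, and 382 and 88 without Cj stem replicate 2. In stem alone Cs9g16810 (log2 fold change 1.48, adjusted p = 0.0864) and Cs6g19380 (0.71, adjusted p = 0.439) did not pass edgeR's quasi-likelihood test, and without Cj stem replicate 1 their stem values were 0.12 and -0.73. The differences from leaf were then 3.92 and 2.42. Without Cj leaf replicate 1 the difference for Cs8g14120 was -2.72. Over all alternative fits the call was lost in 7 of 16 for Cs9g16810 and 9 of 16 for Cs6g19380. For Cs8g14120 it was lost in 6 of 16 and for Cs7g18150 in 2 of 15. DESeq2 gave no adjusted p for Cs7g18150, so that fit, which did not call it, is left out of the 15. Of the 4 IDs above, Cs7g18150 alone passed with the 8 scion libraries, and none passed without Pt stem replicate 1, though their differences there (5.13, 3.87, -3.59 and -2.51) were close to those with all libraries. Cs3g01590, named after its values were seen, had a log2 difference of -2.12 with all libraries (adjusted p = 0.00936, edgeR's quasi-likelihood test). It also passed with the 8 scion libraries alone, with DESeq2 and without each scion library in turn. The other alternative fits were not examined for this ID.

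Leaf and stem of the scion differed far more than either tissue did between rootstocks. Averaged over rootstocks, 11633 of 21261 genes passed, 5717 higher and 5916 lower in leaf, and 5059 of them differed at least 2-fold. DESeq2's size factors gave 6191 higher and 5507 lower, and its Wald test 5501 and 4870. Differences of at least 4-fold were mostly toward stem, with 480 genes higher and 1454 lower in leaf. Orange1.1t00203 stood at 366 ± 15.2 CPM in leaf and 1.79 ± 0.398 CPM in stem on Cj, and at 644 ± 43.9 against 3.11 ± 0.625 CPM on Pt. Cs6g19630 stood at 103 ± 6.14 CPM in leaf and 1.34 ± 0.0900 CPM in stem on Cj, while Cs4g07040 stood at 0.519 ± 0.0216 CPM in leaf and 166 ± 71.1 CPM in stem on Cj. Cs5g13890 stood at 0.299 ± 0.171 CPM in leaf and 97.7 ± 8.09 CPM in stem on Cj (SD, n = 2 each).

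By edgeR's quasi-likelihood test the log2 fold changes, leaf minus stem over both rootstocks, were 7.68 ± 0.13 (SE, adjusted p = 1.5e-11) for orange1.1t00203, 6.09 ± 0.15 (adjusted p = 4.4e-11) for Cs6g19630, -8.09 ± 0.28 (adjusted p = 3.5e-10) for Cs4g07040 and -7.42 ± 0.17 (adjusted p = 1.9e-11) for Cs5g13890. Within Cj alone 9379 genes passed and within Pt alone 8605. In a fit of log2(FPKM + 1) by limma 4545 genes were higher and 7341 lower in leaf, with the median of all genes at -0.10, against 5717 and 5916 on TMM-scaled counts.

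The rootstock differences in roots and in the scion were nearly uncorrelated across genes, though calls in one direction were more numerous than independent lists would give. Of the 613 genes called in both root and stem, 385 had one direction and 228 opposite directions, where independent lists would give 146 higher, 98.9 lower and 241 opposite genes. The observed same-direction genes were 246 higher and 139 lower on Cj (Fisher's exact test across genes, two-sided, p = 1.6e-20 and 6.4e-06). For root and leaf, 576 genes had one direction (307 higher and 269 lower, against 258 and 200 from independent lists) and 471 opposite directions (455 from independent lists). The same Fisher's exact test gave p = 3.3e-04 for the higher and 4.1e-08 for the lower genes of root and leaf. Genes are not independent replicates in either test. Across all 21261 genes Pearson's r of the fold changes was 0.07 for root and stem and 0.01 for root and leaf. The share of root and stem genes with one direction changed with the stem libraries fitted. It was 62.8% with all libraries, 53.8% without Cj stem replicate 1 and 69.5% without Cj stem replicate 2. Without Pt stem replicate 1 or 2 it was 52.8% and 53.3%. No expected numbers were computed for these fits, so what the excess rests on was not tested. For root and leaf they were 439 and 421 without Cj leaf replicate 1, 367 and 233 without Cj leaf replicate 2, 331 and 250 without Pt leaf replicate 1, and 287 and 249 without Pt leaf replicate 2. Of the 414 genes shared by stem and leaf, 153 were called in root in that direction and 106 in the opposite one.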

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

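The tests in this part were chosen before their results were seen, except for the stem values without Cj stem replicate 1. What brought these results here is a difference between 2 tissues: the rootstock effect (Cj minus Pt) in scion stem departed from that in scion leaf by a test of the difference itself. That test, a contrast in edgeR's quasi-likelihood model, called 78 genes, and 51 of them had opposite signs in stem and leaf. The count was 1 without Pt stem replicate 1, 26 without Pt leaf replicate 1, 29 without Pt leaf replicate 2 and 470 without Cj stem replicate 2.

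For Cs9g16810 the log2 fold change was 1.48 in stem and -3.81 in leaf, a difference of 5.29 ± 0.83 (SE). For Cs6g19380 it was 0.71 in stem and -3.15 in leaf, a difference of 3.87 ± 0.66 (SE). Without Cj stem replicate 1 the stem values of Cs9g16810 and Cs6g19380 were 0.12 and -0.73, and the differences were 3.92 and 2.42. In stem alone neither passed edgeR's quasi-likelihood test with all libraries (adjusted p = 0.0864 for Cs9g16810 and 0.439 for Cs6g19380). For Cs8g14120 the log2 fold change was -0.81 in stem and 2.94 in leaf, a difference of -3.75 ± 0.61 (SE), or -2.72 without Cj leaf replicate 1. For Cs7g18150 it was -0.96 in stem and 1.53 in leaf, a difference of -2.49 ± 0.29 (SE). With the 8 scion libraries alone Cs7g18150 still passed (adjusted p = 0.0405), while Cs9g16810 (adjusted p = 0.109), Cs6g19380 (0.144) and Cs8g14120 (0.120) did not, by edgeR's quasi-likelihood test; the differences of the last 3 there were 5.28, 3.85 and -3.76. Without Pt stem replicate 1 none of the 4 passed, with adjusted p of 0.118, 0.148, 0.118 and 0.0735 for Cs9g16810, Cs6g19380, Cs8g14120 and Cs7g18150 in the same test. The differences there were 5.13, 3.87, -3.59 and -2.51, so their size was kept while the calls were lost.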

How the results depend on the processing

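Chosen after the data were seen were the fits without the 2 most abundant root genes, the stem and leaf fits of the 8 scion libraries, the fit of the 8 root and stem libraries, the extra settings for shared genes and the settings for tissue groups. No named ID reversed its direction in the comparison it was chosen for (Cs6g19380, chosen for stem minus leaf, changed sign in stem without Cj stem replicate 1). Outside the stem minus leaf contrast, an ID was named only if all libraries of one side stood above all of the other. Leaving out 1 library could then hardly reverse its sign, so this result was largely fixed in advance. The balance of higher and lower calls turned in some settings for roots, leaf, stem, the stem minus leaf contrast and leaf against stem. It also turned for genes shared by stem and leaf, from 222 higher and 192 lower to 133 and 138 on log2(FPKM + 1). On log2(FPKM + 0.1) these were 49 and 54. Stem-enriched genes in leaf and root-enriched genes in stem, not called with all libraries, passed in opposite directions when one or the other Cj library was left out. The 10994 root calls stayed within 1.5 times (8628 to 9160 when 1 library was left out) except for a minimum log2 fold change of 1, which by construction gave 6295. The 11633 leaf against stem calls did so too (10584 to 11238), with 5059 at that minimum. The 1766 leaf calls fell to 629 at that minimum and 1158 on log2(FPKM + 0.1), and ran from 863 to 1412 when 1 library was left out (863 without Pt leaf replicate 2, 938 without Pt leaf replicate 1 or Cj leaf replicate 2).

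The 941 stem calls fell to 66 with the stem libraries alone, 343 with the 8 scion libraries, 593 on log2(FPKM + 1), 174 on log2(FPKM + 0.1) and 321 at the fold minimum. Leaving out 1 library gave 48 higher and 53 lower (Cj stem replicate 1), 77 and 114 (Pt stem replicate 1), 136 and 150 (Pt stem replicate 2) and 901 and 506 (Cj stem replicate 2). The 78 genes of the stem minus leaf contrast became 184 without a low-count filter, 315 with DESeq2, 3 with the scion libraries alone, 46 on log2(FPKM + 1) and 8 on log2(FPKM + 0.1). Leaving out 1 library gave 1 (Pt stem replicate 1), 26 and 29 (Pt leaf replicate 1 or 2) up to 470 (Cj stem replicate 2). The 414 genes shared by stem and leaf became 47 with each tissue alone, 189 with the scion libraries, 271 and 103 on log2(FPKM + 1) and log2(FPKM + 0.1), and 109 at the fold minimum. Leaving out 1 library gave 76 (Cj stem replicate 1), 133 and 148 (Pt stem replicate 1 or 2) up to 507. The causes of the FPKM, filter and DESeq2 changes were not tested; fewer libraries leave fewer degrees of freedom.

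On log2(FPKM + 1) and log2(FPKM + 0.1) 38.2% and 36.6% of leaf against stem calls were higher in leaf, against 49.1%, with the median of all genes shifted by -0.10 and -0.13. Among 283 repeats of the 20 results for named IDs, 258 kept direction and call and 25 kept direction but not the call. The lost calls were 24 for the 4 IDs of the stem minus leaf contrast and 1 for Cs7g29040. IDs outside that contrast were chosen as the largest changes among called genes with separate libraries. Their kept directions were therefore largely fixed in advance. Of 132 repeats for the 12 tissue group results, 118 kept their side of the threshold, 5 lost the call and 9 gained one. The replicate numbers were not treated as pairs: deviations of same-numbered libraries correlated between -0.06 and 0.13 over the 15 pairs of groups. With the replicate number as a block, calls were 10904 in roots, 983 in stem, 1801 in leaf, 112 for the stem minus leaf contrast, 11545 for leaf against stem and 436 shared by stem and leaf; of these, 10746, 884, 1671, 73 and 11430 were the same genes as without the block for the first 5. The planned gene list tests were not run, because no ID could be paired with a description. Depth limits genes of low count, and 5298 listed genes were not tested.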

Other observations

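Set before their results were seen were the tests on reads divided between copies and on other splits of the scion libraries; the other tests in this part were chosen only after. Genes that differed between rootstocks often stood next to each other in ID order. In leaf 163 pairs of consecutive tested IDs were called in one direction, against a mean of 66.3 and a highest value of 90 in 1000 shuffles of the calls. In stem there were 71 pairs, against 19.9 and 36, and in roots 2941 pairs, against 2461 and 2601. The permutation p was 0.001 each time, the smallest that 1000 shuffles can give. Neighbouring IDs need not be neighbours in the genome, since no coordinates were used here.

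Roots differed from both scion tissues in most genes. Averaged over rootstocks, 17996 of 21261 genes passed edgeR's quasi-likelihood test between root and stem (7935 higher and 10061 lower in root) and 18167 between root and leaf (8472 higher and 9695 lower). Tissue and species differ together in this contrast. Cs7g25130 was higher in root than in stem by a log2 fold change of 9.15 ± 0.25 (SE) and orange1.1t01308 by 7.17 ± 0.20, both picked after their values were seen.

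The number of genes called between the roots is the first pattern weighed. Plain loss of Pt reads would leave few genes much higher in Pt roots, and 848 genes were at least 4-fold higher there. This argues against plain loss as the whole account. It does not weigh against Pt reads assigned to a wrong copy, which could raise a gene in Pt roots. Counts are also scaled relative to other genes, so loss in many genes could raise the rest. Poorer alignment of Pt reads could still add to the 1899 genes at least 4-fold higher in Cj roots. A few genes taking most of the counts is argued against as well: the shares of the 2 most abundant genes would shift all others by a log2 change of at most 0.0510 between a Cj and a Pt root library, against a median absolute log2 fold change of 1.16 in the called genes. Alignment loss in either species, gene by gene, stays open because species and alignment change together. A difference in expression between the rootstock species is the biological explanation that stays open beside it, and may account for part of the 10994 calls.

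The run Cs4g17220, Cs4g17230 and Cs4g17240, and neighbouring calls in general, are the second pattern. RNA moving from the Pt rootstock into the scion is argued against, since the highest level of the 3 IDs in a Pt root was 2.08 CPM and the lowest in a Pt scion library 26.5 CPM. As to a single aberrant library, the lowest Pt scion value exceeded the highest Cj scion value at least 10.9-fold for each ID. Separate libraries were a condition for naming an ID in a tissue, so this gap was in part fixed in advance. Cs4g17220 in stem and Cs4g17230 in leaf were not named by that rule. There the highest Cj value was 0.579 and 13.5 CPM and the lowest Pt value 26.5 and 547 CPM, which argues against a single library for these. Reads divided between near-identical copies would give fractional counts, yet among 12729 tested IDs with whole counts in all libraries 98 leaf pairs were seen against at most 76 in shuffles. In roots there were 2036 against at most 1866. In stem there were 37 against at most 33, a narrower margin than the 71 against at most 36 with all such IDs. Reads assigned whole to one of several copies stay open. For neighbouring calls in general, genes that vary together between libraries stay open too, since the shuffles treat genes as independent. A candidate explanation is a group of adjacent scion genes that responds to the rootstock together, or a difference between the scion trees themselves, and no test here separates these.

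The number of genes called in scion stem is the third pattern. Of the stem libraries on Cj, replicate 1 stood further from those on Pt (Pearson's r 0.974 and 0.973) than replicate 2 did (0.980 and 0.983). Root libraries varied less than scion libraries (biological coefficient of variation 7.09% in root and 14.1% in stem), and a shared estimate of spread may therefore call too many stem genes. On the same 21027 genes and with 4 residual degrees of freedom each, 1035 stem genes were called with the 8 root and stem libraries and 421 with the 8 stem and leaf libraries, which fits that account; neither fit tells which count is nearer the truth. A single stem library cannot be told apart from chance with 2 libraries per group: leaving out Cj stem replicate 2 raised the count to 1407, and leaving out Cj stem replicate 1, Pt stem replicate 1 or Pt stem replicate 2 lowered it to 48 higher and 53 lower, to 191 or to 286. A real rootstock effect in stem stays open, with 42 genes called with all libraries, with the stem libraries alone, by DESeq2 and without each stem library in turn.

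For leaf against stem, other splits of the scion libraries were tried to weigh chance as the source of the calls. Of the 35 splits of the 8 scion libraries into 4 and 4, only 1, the real one, gave as many calls, 9344 in a model of those 8 libraries with 2 groups, and the highest other gave 12. That other split was the one by rootstock. Every split but the real one puts stem and leaf libraries in the same group. The tissue difference then widens the spread within groups and keeps the calls low. For this reason, and with only 35 splits, the test cannot exclude chance.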
